A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

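Gene expression was measured in 6 cultures of the budding yeast Saccharomyces cerevisiae, strain background W303, a common laboratory strain. Per the labels' protocols, cells grew in rich medium (YPD) at 30 °C to log phase, and labelled cRNA was made from 10 µg of total RNA for an Affymetrix array. The labels put 3 arrays in the wild-type group and 3 in the rph1 deletion group, numbered 1 to 3 in each, and the series' design text calls the samples biological. No source used here says whether cultures with the same number were grown together.

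The deposited values are signal intensity per probe set on a linear scale, made with MAS5, the Affymetrix summary method, per the submitters' processing notes. The MAS5 version and the scaling target are not given in the sources used here. The 2% trimmed mean of the signals was 500.2 on every array, so the table was taken as already scaled and used as deposited. The log2 of each signal was taken for testing.

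The array carries 10928 probe sets. Of these, 166 are AFFX controls, 47 are reporter probe sets for sequences used in strain construction or assays, and 7244 are listed with 1 gene symbol and 1 with several. A further 3470 were unlisted in the probe annotation used here. Matching gene identifiers to the RefSeq gene table (assembly R64) assigned 5498 probe sets to 1 S. cerevisiae gene each, and 1746 belong to the fission yeast Schizosaccharomyces pombe, which the same array also covers. The assembly was used for names and for which genes are neighbours, and no coordinates are printed because the files name no build. The S. cerevisiae probe sets cover 5449 genes. For the 47 genes with more than 1 probe set, the one with the highest mean was kept. In 43 of these that could be compared, the fold changes of the probe sets differed by a median of 0.042 on the log2 scale, and by 0.50 at most, for YPL277C.

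Fission yeast probe sets served as the measure of background. A gene was tested if its mean log2 signal over all 6 arrays exceeded the 95th percentile of the fission yeast means, 3.06 (a signal of 8.32). This kept 5402 genes and left out 47. Of the tested genes, 111 were measured on probe sets that the manufacturer marks as able to cross-hybridise, so their values are uncertain between related genes. On single arrays the same percentile lay between signals of 8.59 and 12.7, and 99.2% to 99.83% of tested genes lay above it. A gene at or under that level has only a bound. For it, a fold is given as "at least", from the bright group's mean over the mean of the higher of background and the gene's own signal on each dim array. Precision is limited by the number of arrays.

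The comparison was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 signals, genotype as the only term, 2-sided), with Benjamini-Hochberg adjustment over the 5402 genes and a threshold of 0.05. Standard errors (SE) of log2 differences come from this fit. A value written with SD is a mean over 3 arrays. Single values were also compared by an exact permutation test, which cannot go below p = 0.1 with 3 arrays against 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

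A set of 34 gene lists, fixed before the data were examined, was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with a correlation estimated from the arrays, and fry, which asks whether a list's genes move on balance one way, were alternatives. The test, filter, lists and alternatives were set before the data were examined, except 2 alternatives, named with the other settings, and 1 further list of nitrogen-regulated genes. The genes named were also chosen by rule. They are RPH1, its neighbours CCA1 and ADK2, its paralog GIS1, and PHR1; then the 12 largest changes past the threshold in each direction, or all of them if fewer, filled up to 6 by the smallest unadjusted p; then up to 4 members with the smallest unadjusted p of each list described. Genes named outside this rule are said to be so.

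The replicate numbers were checked for pairing before the fits were compared. Deviations from the group means, correlated across genes between same-numbered arrays, gave 0.768, 0.454 and 0.415 for replicates 1, 2 and 3, all above 0.1, so the numbers were taken to pair the arrays. The pairing comes mainly from a split of replicate 1 from the others. Wild type 3 correlated more with deletion 2 (0.535) than with deletion 3, and wild type 2 slightly more with deletion 3 (0.471) than with deletion 2. These values therefore do not show that replicates 2 and 3 are paired by number. The labels give the replicate 1 arrays a different form of sample code. A spiked control RNA, dap, read 0.0959 and 2.02 on the wild-type and deletion arrays of replicate 1, and between 42.7 and 55.0 on the other 4 arrays. This split was treated as a batch. Each batch holds both genotypes, so values are also given with the replicate number as a block, with the batch as a term, and within replicates 2 and 3. The replicate 1 batch has 1 array per genotype and gives a difference with no test.

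The procedure was tested on simulated data for this comparison. With 5402 genes and 200 changed per draw over 10 draws, the same fit recovered 57.5% of 1.5-fold, 83.3% of 2-fold and 95.9% of 4-fold changes, with a mean of 8.1 unchanged genes called. The simulated arrays held no batch and no correlation between genes. The adjusted threshold is easier to reach where many genes change, as the 200 did here. These shares therefore do not give the recovery in data where few genes change. A simulated shift of 0.25 in the autophagy list was called in 10 of 10 draws with the preset and 8 of 10 with the estimated correlation, and in 0 draws with no shift. With genes drawn independently, this cannot show how often the preset correlation calls a list wrongly where genes vary together.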

Results

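The data are 6 arrays of log-phase yeast in rich medium, 3 of wild type and 3 of a strain deleted for RPH1. RPH1 encodes a zinc-finger protein with a JmjC histone demethylase domain, known as a repressor of the DNA repair gene PHR1. The comparison asks which genes Rph1 regulates during unstressed growth, with DNA damage signalling and the general stress response as the stated interests. Median signals over the tested genes lay between 598.8 and 628.1 on the 6 arrays, and the arrays correlated with each other across genes at 0.9717 to 0.9957.

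RPH1 itself checked the labels. Its signal was 305, 362 and 385 in wild type 1, 2 and 3, and 4.52, 8.18 and 8.99 in the same-numbered deletion arrays. The log2 difference was -5.66 (SE 0.27, limma adjusted p = 0.00196). Only 1 of the 3 deletion arrays read above background, so the drop is given as at least 35.2-fold. The exact permutation test gave p = 0.1, the smallest it allows. Of the neighbouring genes, CCA1, encoding the tRNA nucleotidyltransferase, differed by -0.05 (SE 0.11). ADK2, encoding a mitochondrial adenylate kinase, read 301 ± 24 (SD, n = 3) in wild type and 403 ± 39 (SD, n = 3) in the deletion, a log2 difference of 0.42 (SE 0.10). It was higher on all deletion arrays but did not pass (limma adjusted p = 0.435). The paralog GIS1 differed by 0.11 (SE 0.08) and PHR1, the photolyase gene, by 0.18 (SE 0.09), and neither passed (limma adjusted p = 1.00 for both).

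**Figure D1:**
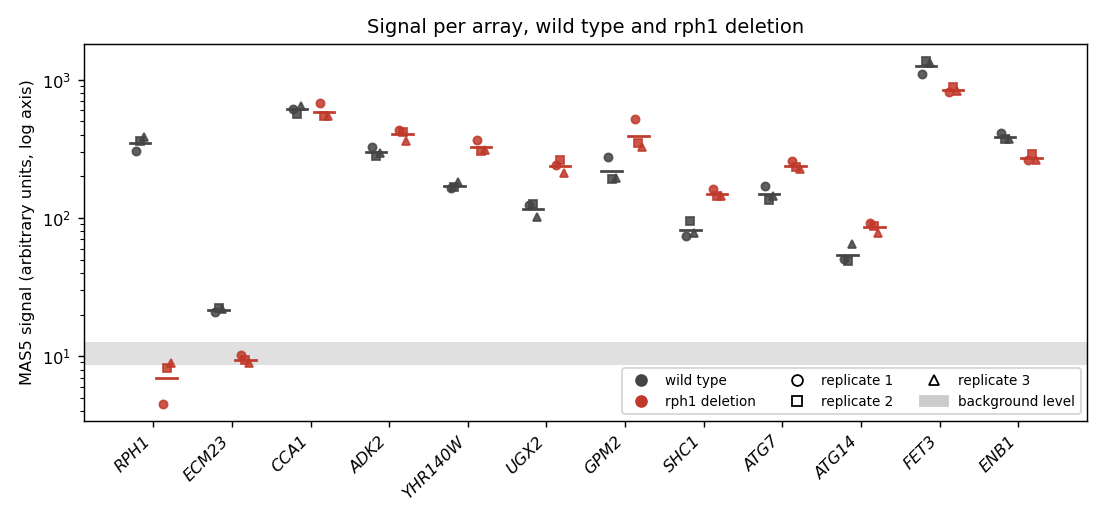
MAS5 signal (arbitrary units, log axis) of 12 genes on each array, wild type in grey and rph1 deletion in red. Symbols mark the replicate number, short lines the geometric mean of 3 arrays, and the grey band the range of background over the arrays. RPH1 drops from 305 to 385 into or under the band, and ECM23 also reaches it. The other genes shown differ by smaller steps and GPM2 was picked after its values were seen.

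Beyond RPH1, 1 gene passed the test. ECM23, encoding a GATA-type zinc-finger protein, fell from 21.7 ± 0.71 to 9.46 ± 0.63 (SD, n = 3 each), a log2 difference of -1.20 (SE 0.08, limma adjusted p = 0.00871). It lies close to background, with 1 of 3 deletion arrays above it, and was at least 2.07-fold lower. The call was lost when any 1 of 5 arrays, all but deletion replicate 1, was left out, though the log2 difference stayed at -1.23 to -1.16 in those cases. It was also lost after quantile normalization (-1.03, adjusted p = 0.280), with an intensity trend (-1.20, adjusted p = 0.299) and with an offset of 32 (-0.37, adjusted p = 0.235). In all, limma called 2 genes lower and 0 higher of 5402. At an unadjusted p under 0.05 there were 288 genes, 234 higher and 54 lower, where 270 are expected by chance with no batch. In the same fit the 5 other groupings of the arrays that keep the batches balanced gave 28 to 59 genes. Groupings that follow the batch gave 441 to 1248, so 270 is not the level that wrong groupings give here. In 408 genes (7.55%) every deletion array was above every wild-type array, and in 164 (3.04%) every one was below. Chance gives 5% each way with no batch. The unadjusted balance of higher and lower genes depended on scaling. Higher genes made up 81.2% of the 288 as deposited, 69.2% after quantile normalization and 66.0% after median centring.

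The batch mattered for these counts. With the replicate number as a block, limma called 6 genes, 3 higher and 3 lower. They were RPH1, ECM23, UGX2, GPM2, AZR1 and YLR031W, the last 3 named because they make up this count. With the batch as a term it called 34, 29 higher and 5 lower, among them all 6 of those. Within replicates 2 and 3 alone it called 2, both lower, the same genes as over all arrays. At an unadjusted p under 0.05 the block gave 701 genes (508 higher, 193 lower), the batch term 786 (564 higher, 222 lower) and replicates 2 and 3 alone 572 (406 higher, 166 lower), against the same 270 by chance.

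The genes next in line were higher in the deletion without passing over all arrays. YHR140W, an uncharacterised gene, had a log2 difference of 0.93 (SE 0.10, limma adjusted p = 0.0978). UGX2, a stress-responsive gene of unknown function, differed by 1.02 (SE 0.12), and SHC1, an activator of chitin synthase III in sporulation, by 0.87 (SE 0.12). HVG1, related to the Golgi nucleotide-sugar transporter Vrg4, differed by 0.68 (SE 0.08). DOA4, a ubiquitin hydrolase that recycles ubiquitin from cargo bound for the vacuole, differed by 0.65 (SE 0.08). RMR1, linked to meiotic recombination, differed by 0.52 (SE 0.08). The limma adjusted p of these 5 was 0.130 to 0.224, and all 6 genes were called with the batch as a term (adjusted p = 0.0281 to 0.0422). UGX2 alone of the 6 was called with the replicate block (adjusted p = 0.0241). On the other side, the mitochondrial chaperone gene ECM10 differed by -0.60 (SE 0.08), the multicopper iron oxidase gene FET3 by -0.56 (SE 0.10), the siderophore transporter gene ENB1 by -0.51 (SE 0.08) and the meiotic chromosome gene HOP1 by -0.44 (SE 0.08). None of these passed (limma adjusted p = 0.186 to 0.320). ECM10 (adjusted p = 0.0349) and FET3 (adjusted p = 0.0400) were called with the batch as a term.

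Of the 34 gene lists, camera with the preset correlation called 7, 3 up and 4 down. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 2. Lists are described by the median log2 difference of their measured members.

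Autophagy genes, which build and deliver the vesicles that carry cytoplasm to the vacuole, rose together. Of 29 measured, 26 were higher in the deletion and the median was 0.27 (camera adjusted p = 5.84e-14). The call was lost with an estimated correlation (p = 0.00436, adjusted p = 0.148), and fry kept it (adjusted p = 0.0234). Adjusted over the list alone, 8 genes passed, all higher, and 0 passed over all genes tested. With the batch as a term 1 of them, ATG7, did (adjusted p = 0.0259). ATG7, encoding the E1-like enzyme of the conjugation systems, read 150 ± 19 in wild type and 239 ± 16 in the deletion (SD, n = 3 each), a log2 difference of 0.67 (SE 0.11). ATG14, a subunit of the autophagy lipid kinase complex, differed by 0.66 (SE 0.13). ATG33, which acts in mitophagy, differed by 0.49 (SE 0.09), and ATG31, of the starvation scaffold complex, by 0.35 (SE 0.07). Within replicates 2 and 3 the median was 0.24, and in the replicate 1 pair 0.26. With the block the camera adjusted p was 6.73e-11, and 0.743 with the estimated correlation as well. Camera with both has few degrees of freedom and called 0 of the 34 lists, so that loss decides little.

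Genes of the iron regulon, the targets of the low-iron activator Aft1, fell. Of 25 measured, 20 were lower and the median was -0.17 (camera adjusted p = 6.98e-07). With an estimated correlation the p was 0.0245 and the adjusted p = 0.416, and fry did not call the list (adjusted p = 0.142). FET3 and ENB1 passed adjusted over the list alone and 0 genes passed over all genes tested, or FET3 alone with the batch as a term. The siderophore transporter gene ARN2 differed by -0.30 (SE 0.10) and the vacuolar ferric reductase gene FRE6 by -0.24 (SE 0.08). The median was -0.14 within replicates 2 and 3 and -0.15 in the replicate 1 pair. It ranged from -0.25 to -0.11 when single arrays were left out, the call holding each time.

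**Figure D2:**
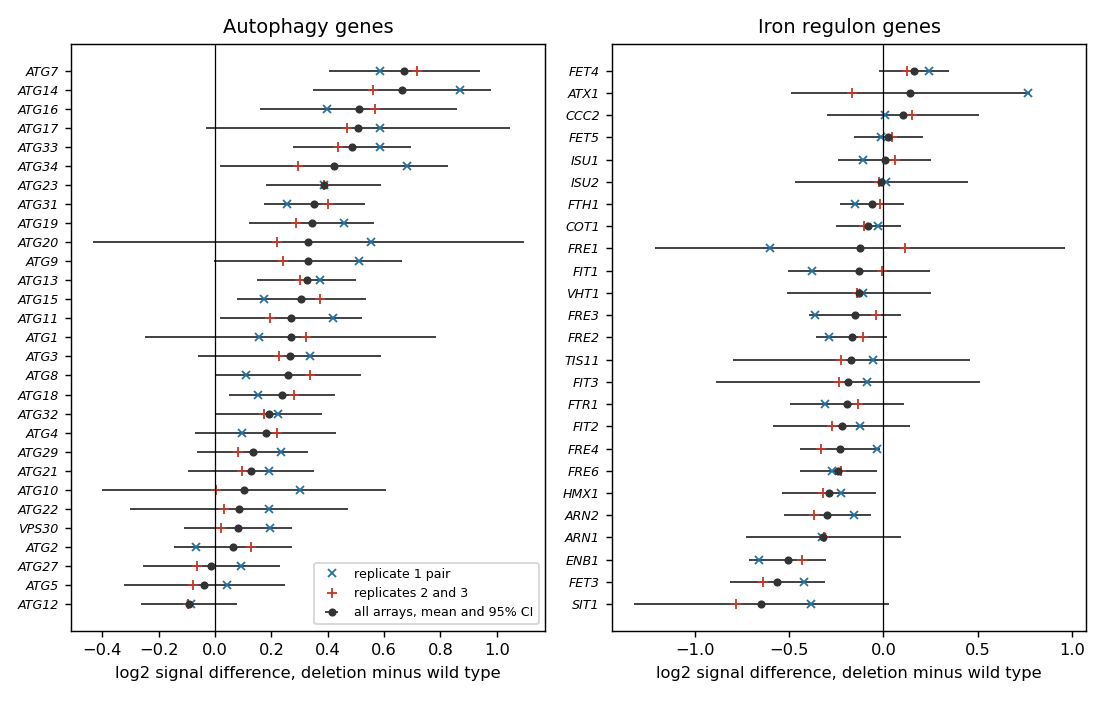
Log2 signal difference, deletion minus wild type, of each measured autophagy gene (left) and iron regulon gene (right). Points with bars are the limma estimate over all arrays with its 95% confidence interval, crosses the replicate 1 pair and plus signs replicates 2 and 3. Of the autophagy genes 26 of 29 lie above 0, and of the iron genes 20 of 25 lie below it.

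The Msn2/4 general stress genes, the set induced by many stresses, rose by a small median of 0.10, with 47 of 59 measured members higher (camera adjusted p = 0.0106). The call was lost with an estimated correlation (p = 0.247, adjusted p = 0.788) and with fry (adjusted p = 0.689). UGA2, encoding succinate semialdehyde dehydrogenase, was the 1 gene that passed adjusted over the list alone, at 439 ± 53 in wild type and 709 ± 54 in the deletion (SD, n = 3 each). It had a log2 difference of 0.70 (SE 0.11). GRE1, a gene induced by osmotic stress, differed by 0.74 (SE 0.16), DCS1, which acts on the mRNA cap left after decay, by 0.30 (SE 0.07) and SDS24 by 0.42 (SE 0.16), and 0 members passed over all genes tested. With the batch as a term UGA2 and SDS24 did (adjusted p = 0.0400 for each). The median was 0.078 within replicates 2 and 3 and 0.24 in the replicate 1 pair. Without deletion replicate 1 it was 0.0031 (adjusted p = 0.596), without wild type replicate 2 it was 0.044 (adjusted p = 0.174), and without wild type replicate 3 the adjusted p was 0.0946. Of the other splits of the 6 arrays into 3 and 3 that keep the batches balanced, 1 of 5 gave a larger median for this list.

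For DNA damage response and repair genes no shift passed the test. Of 42 measured, 26 were higher, the median was 0.020 and camera gave an adjusted p of 0.599. No member passed adjusted over the list alone (0 genes) or over all genes tested, and 1 had an unadjusted p under 0.05. This was DIN7, a mitochondrial nuclease gene, at 0.22 (SE 0.08). RAD5 differed by 0.15 (SE 0.07) and RAD2, an excision repair nuclease gene, by 0.42 (SE 0.21).

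Respiratory chain and ATP synthase genes rose slightly (median 0.044, 30 of 38 higher, camera adjusted p = 0.0172), a call lost with an estimated correlation (adjusted p = 0.756). The members with the smallest p were the succinate dehydrogenase genes SDH2 (0.29, SE 0.07) and SDH1 (0.25, SE 0.09) and the NADH dehydrogenase genes NDI1 (0.23, SE 0.07) and NDE2 (0.47, SE 0.18). Adenine and one-carbon synthesis genes fell (median -0.15, 15 of 16 lower, camera adjusted p = 0.000231; 0.756 with an estimated correlation). GCV3 differed by -0.22 (SE 0.09), MTD1 by -0.26 (SE 0.11), ADE8 by -0.18 (SE 0.09) and ADE2 by -0.29 (SE 0.16). The median was -0.11 within replicates 2 and 3 and -0.28 in the replicate 1 pair, and without deletion replicate 1 it was -0.042 (adjusted p = 0.132). Cytosolic ribosomal protein genes were lower in 111 of 127, by a median of -0.041 (camera adjusted p = 0.00227; 0.798 with an estimated correlation). That call did not hold within replicates 2 and 3 (median -0.018, adjusted p = 0.249), and the direction turned without wild type replicate 1 (median 0.030, adjusted p = 0.313). It was also lost after quantile normalization (adjusted p = 0.807) and without deletion replicate 2 (0.0558) or 3 (0.128). RPL8A, at -0.10 (SE 0.08), had the smallest p among them. The 7 a-cell-specific genes, a check on mating type, had a median of -0.19 (camera adjusted p = 0.0172; 0.756 with an estimated correlation), with STE2, the alpha-factor receptor gene, at -0.28 (SE 0.08) and a mean signal of 64.9 in wild type and 53.4 in the deletion. BAR1, also a-cell-specific, read 81.4 and 74.9. The alpha-cell-specific genes STE3 (2025 in wild type, 1970 in the deletion) and MF(ALPHA)1 (5763 and 5802) were bright in both. By these genes both strains read as alpha cells, and no change of mating type is seen. Several settings ended the a-cell call and the one for respiratory chain genes. For a-cell genes these were replicates 2 and 3 alone (median -0.20, adjusted p = 0.124), median centring (-0.22, 0.0580), array weights (-0.11, 0.144), quantile normalization (-0.18, 0.101) and an intensity trend (-0.19, 0.0852). Leaving out deletion replicate 1 brought the median to -0.086 (0.378), wild type replicate 3 to -0.14 (0.129) and wild type replicate 2 to -0.14 (0.151). For respiratory genes they were replicates 2 and 3 alone (0.028, 0.254), median centring (0.0086, 0.0600), array weights (0.017, 0.319), and leaving out deletion replicate 1 (0.028, 0.349) or wild type replicate 3 (0.043, 0.235).

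Among lists with no camera call over all arrays, antioxidant defence genes were called by fry alone (adjusted p = 0.0161; camera adjusted p = 0.386, median 0.0038). The glutathione peroxidase gene HYR1, at 0.40 (SE 0.07), passed adjusted over that list, and the peroxiredoxin gene DOT5 differed by 0.29 (SE 0.07). Glycogen and trehalose genes did not pass (median 0.017, adjusted p = 0.484), and the glycogenin gene GLG2, at 0.58 (SE 0.11), passed over that list. With the batch as a term HYR1 (adjusted p = 0.0422) and GLG2 (0.0400) passed over all genes tested. The block brought 4 further lists past the threshold, 11 in all, each of the 4 losing its call with an estimated correlation (adjusted p = 0.772 for each). With the block that version of camera has few degrees of freedom and called 0 of the 34 lists, so these losses decide little. With the batch as a term 10 lists passed, without the glucose-repressed genes (0.0522). The 4 were sulfur and methionine metabolism (median -0.068, blocked adjusted p = 0.00987, 0.116 without the block), seripauperin genes (median -0.10, 0.0323 and 0.0827), amino acid biosynthesis (median -0.038, 0.0403 and 0.0827) and glucose-repressed genes (median 0.12, 0.0479 and 0.0827). Within replicates 2 and 3 sulfur genes had a median of -0.0097 and amino acid genes of 0.0031 (adjusted p = 0.930 for each), against -0.25 and -0.11 in the replicate 1 pair. Seripauperin genes (-0.16, adjusted p = 0.000653) and glucose-repressed genes (0.18, adjusted p = 0.0198) passed there, against -0.026 and 0.032 in the replicate 1 pair.

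The remaining lists did not pass over all arrays. Tricarboxylic acid cycle genes had a median of 0.063 (camera adjusted p = 0.158), and passed within replicates 2 and 3 (median 0.076, adjusted p = 0.0264) and after quantile normalization (median 0.059, adjusted p = 0.0414), while the estimated correlation over all arrays gave 0.756. Medians were -0.058 for glycolysis and fermentation (0.158), 0.026 for hexose transporters (0.737), -0.024 for phosphate starvation genes (0.719) and -0.033 for ergosterol synthesis (0.214). They were -0.017 for ribosome biogenesis (0.151), 0.023 for mitochondrial ribosomal proteins (0.432) and -0.017 for the proteasome (0.158). Cell cycle lists gave -0.014 for G1/S (0.510), 0.044 for G2/M (0.224) and -0.018 for M/G1 and daughter-cell genes (0.373). Histones gave -0.046 (0.242), COS genes 0.046 (0.554), alpha-cell-specific genes 0.058 (0.801) and meiosis and sporulation genes -0.042 (0.386), with 1 gene, HOP1, passing over that last list alone. Msn2/4 and stress regulators, with RPH1 itself a member, gave -0.0024 (mean -0.42, adjusted p = 0.349), and without RPH1 0.016 (mean 0.013, adjusted p = 0.891). In 4 lists median and mean differed in sign. They were histone lysine methylation enzymes, which also hold RPH1 (median 0.0021, mean -0.47, adjusted p = 0.589, and without RPH1 0.053, 0.053 and 0.513), heat shock proteins (median -0.025, mean 0.020, adjusted p = 0.863, test direction down), pheromone response (median 0.047, mean -0.0065, adjusted p = 0.801) and W303 auxotrophic markers (median 0.015, mean -0.017, adjusted p = 0.719).

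**Figure D3:**
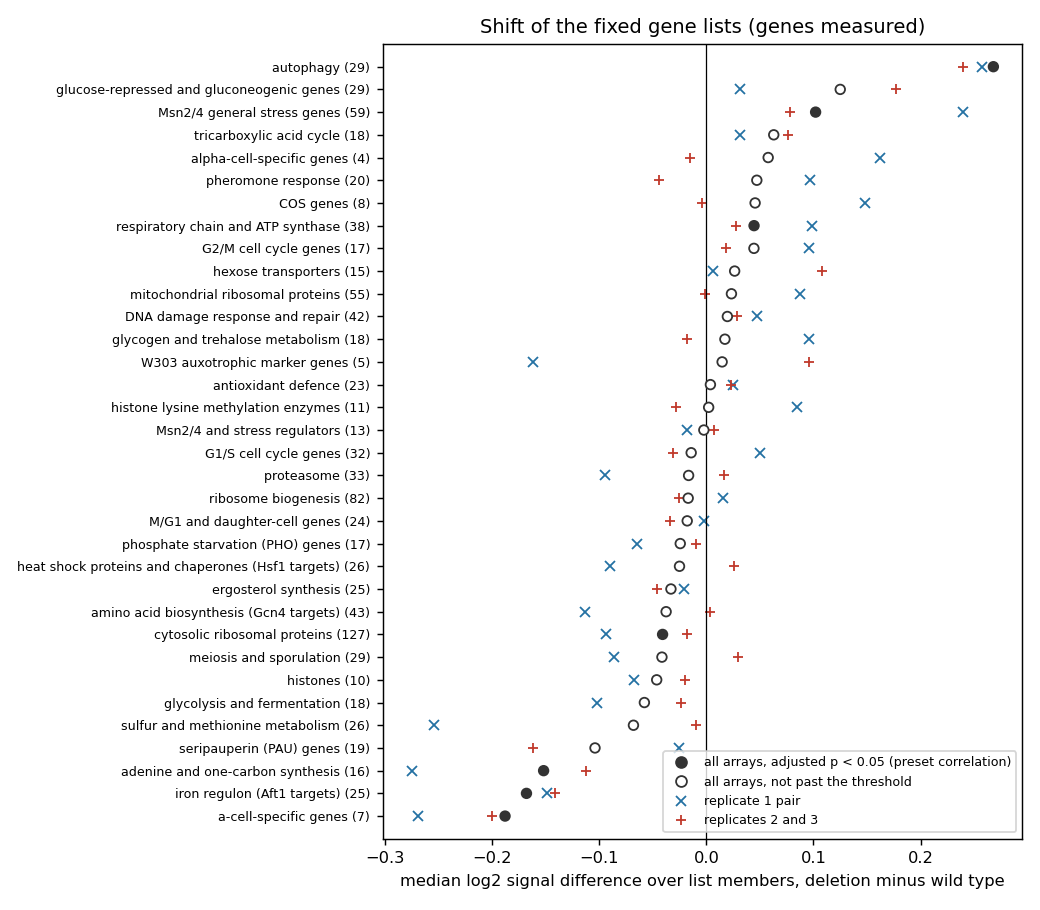
Median log2 signal difference, deletion minus wild type, over the measured members of each of 34 gene lists, with the number of genes in brackets. Circles are all 6 arrays, filled where camera with the preset correlation passed; crosses are the replicate 1 pair and plus signs replicates 2 and 3. Autophagy lies highest at 0.27, and 7 circles are filled.

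As a check of RNA quality, the 3'/5' signal ratios of control genes were compared. The ACT1 ratio was 1.11 ± 0.086 in wild type and 1.06 ± 0.053 in the deletion (SD, n = 3 each, exact permutation p = 0.4), and those of WBP1 and SPT15 gave exact permutation p = 1 and 0.7. The 5.8S ribosomal RNA control was higher on every deletion array, at 971 ± 69 in wild type and 1510 ± 295 in the deletion (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The probe sets for 18S and 25S ribosomal RNA overlapped between genotypes. Of 99 array controls above background, 5 separated the genotypes, 3 higher and 2 lower, where chance gives 10%.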

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

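The tests of this part were set before their results were seen. A reporter-type probe set, outside the genes compared above, was bright in the deletion arrays alone. It read 7830, 6650 and 6540 in deletion replicates 1, 2 and 3 (mean 7006) and 6.39, 7.80 and 8.39 in wild type, where it was not above background on any array. It was at least 612-fold higher in the deletion (limma adjusted p = 1.01e-06). The probe set's identifier carries a sequence accession, which the tables used here do not pair with a gene name. A second probe set with that accession stayed under background on all 6 arrays. Of the other 46 reporter probe sets, 10 were above background on every array of a group. Their median log2 difference was -0.24 (range -0.75 to 0.11), so these did not rise as a class. They were above background on all wild-type arrays too, so they cannot show whether reporter sequences absent from wild type would rise. A higher background on the deletion arrays is argued against by the fission yeast probe sets, whose median log2 difference was -0.26 (95% bootstrap interval over probe sets, -0.31 to -0.21). A transcript from a marker cassette carried by the deletion strain is a candidate explanation that these values go with. Whether the strain carries such a cassette, and which, stays open.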

How the results depend on the processing

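Array weights estimated gene by gene, and the lists without RPH1, were added after the data were seen. RPH1 kept its direction and its call under every setting run (log2 -5.84 to -3.28). The count of 2 genes, both lower, became 1 (lower) after quantile normalization, with the stricter filter, with an offset of 32 and with an intensity trend, RPH1 being the gene left, and ranged from 1 to 2 when single arrays were left out. It was 6 (3 higher) with the replicate block, 34 (29 higher, 5 lower) with the batch term, 30 (21 higher, 9 lower) at unadjusted p under 0.05 and 1.5-fold, and 1 gene was higher at adjusted p under 0.1. Array weights gave 202 (175 higher, 27 lower), from an estimation that warned of not converging, and 50 (44 higher, 6 lower) gene by gene. The first fit put weights of 0.253 and 0.213 on the replicate 1 arrays and of 0.640 on wild type 3, against 4.28 on wild type 2, so its wild-type side leans on that array. Gene by gene the replicate 1 weights were 0.294 and 0.247. The cause of the other changes was not tested.

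Of the 32 lists other than stress and DNA damage, 6 were called in the main setting and without RPH1, 10 with the replicate block, 9 with the batch term, 2 with fry, 0 with an estimated correlation, and 5 to 10 with single arrays left out. The blocked calls for the lists were lost with an estimated correlation, where camera with the block has few degrees of freedom and could hardly call any list. The stress list was not called with an estimated correlation (median 0.10, adjusted p = 0.788) or fry (0.10, adjusted p = 0.689), and its median ranged from 0.0031 to 0.19 with single arrays left out. The autophagy list stayed up with medians of 0.20 to 0.32 and the iron list down with medians of -0.25 to -0.10 under every setting, -0.25 without wild type replicate 1 and -0.11 without deletion replicate 1. Both lost their calls with an estimated correlation, and iron also with fry. The DNA damage list, never called, had a median of 0.014 with a turned test after quantile normalization, -0.016 after median centring, and -0.0081 to 0.066 with single arrays left out.

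Lists with no call in the main setting turned direction, in median or test, as follows. Without RPH1 the stress regulators gave 0.016 and the histone methylation enzymes 0.053, both up. Quantile normalization gave 0.0045 for heat shock, 0.0059 for meiosis, -0.019 for W303 markers and -0.010 for phosphate genes. Median centring gave -0.034 for histone methylation enzymes, -0.021 for W303 markers, -0.013 for mitochondrial ribosomal proteins, -0.032 for antioxidant, -0.019 for glycogen and -0.0096 for hexose transporters. Fry gave -0.025 for heat shock and 0.047 for pheromone response, its direction differing from the test's. Array weights gave -0.058 for alpha-cell genes, 0.070 for meiosis, -0.047 for pheromone response, 0.012 for sulfur, -0.0064 for mitochondrial ribosomal proteins, -0.041 for glycogen, 0.027 for stress regulators and -0.039 for the gene GPH1. Replicates 2 and 3 alone gave 0.096 for W303 markers, -0.0038 for COS genes, -0.028 for histone methylation enzymes, 0.030 for meiosis, -0.044 for pheromone response, -0.016 for alpha-cell genes, -0.0097 for sulfur, 0.017 for the proteasome, -0.00087 for mitochondrial ribosomal proteins, -0.018 for glycogen, 0.0070 for stress regulators, 0.0031 for amino acid synthesis, 0.026 for heat shock and -0.076 for GPH1.

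With single arrays left out, medians ranged from -0.024 to 0.031 for stress regulators, -0.040 to 0.012 for heat shock, -0.096 to 0.030 for cytosolic ribosomal proteins, -0.15 to 0.048 for glycolysis and -0.083 to 0.013 for ergosterol. They ranged from -0.077 to 0.080 for histone methylation enzymes, -0.047 to 0.13 for G2/M, -0.067 to 0.040 for G1/S, -0.12 to 0.061 for M/G1 and -0.066 to 0.13 for W303 markers. They ranged from -0.098 to 0.14 for glycogen, -0.025 to 0.072 for mitochondrial ribosomal proteins, -0.065 to 0.062 for the proteasome, -0.16 to 0.12 for phosphate genes, -0.074 to 0.026 for amino acid synthesis and -0.18 to 0.12 for sulfur. They ranged from -0.084 to 0.11 for alpha-cell genes, -0.054 to 0.074 for pheromone response, -0.11 to 0.069 for meiosis, -0.0047 to 0.083 for COS genes and -0.022 to 0.13 for hexose transporters. GPH1 ranged from -0.012 to 0.38 and CCA1 from -0.15 to 0.0020. Over all settings 945 of 1000 values of the 59 named genes other than RPH1, and 464 of 608 list values, kept direction and side of the threshold. Of list values, 37 passed where the main one had not, among them ergosterol (adjusted p = 0.0124) and glycolysis (0.0164) with array weights and glucose-repressed genes after median centring (0.0386). Without single arrays G2/M, M/G1, ergosterol, glycolysis, mitochondrial ribosomal protein, proteasome, amino acid, glucose-repressed, seripauperin and sulfur lists passed in at least 1 case. ECM23 lost its call without any 1 of 5 arrays, at log2 differences of -1.23 to -1.16. An upstream motif search was not run because no genome sequence was used here.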

Other observations

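The tests of the batch for the autophagy and iron lists, and of iron genes varying together, were chosen after the results were seen. With the batch as a term, limma called 29 genes higher in the deletion, and several named here were chosen after their values were seen. GPM2, a homologue of phosphoglycerate mutase, differed by 0.84 (adjusted p = 0.0106), in both the replicate 1 pair (0.91) and replicates 2 and 3 (0.81). The vacuolar mannosidase gene AMS1, cargo of the selective autophagy route, differed by 0.63, GSP2, a Ran GTPase gene, by 0.57, and the glutathione transferase genes GTT1 and ECM4 by 0.54 and 0.46. AZR1, a drug transporter gene, differed by -1.20, with signals of 268 and 104 in replicate 1 and of 10.6 to 25.9 on the other arrays.

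The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2 genes, 2 of them lower, and the highest of the others called 1 (1 lower), so 1 of 10 splits reached the real count. The 2 genes were RPH1, which the deletion itself removes, and ECM23. Beyond the deleted gene the real split called 1 gene, as many as the highest other, so this count does not set the real split apart. For lists the real split called 7, and 8 of 10 splits called as many, the highest 16, in 2 splits that put both replicate 1 arrays together and so follow the batch. Among the 4 splits that part all 3 pairs, the highest other called 12 lists and 1 gene. With the batch term, 6 splits keep batches balanced, again too few, and the real one called 34 genes and the highest other 0 (1 of 6). At an unadjusted p under 0.05 the real one gave 786 and the highest other 335. The number of lists called with the preset correlation therefore does not set the real grouping apart. Each other split holds both genotypes on both sides in unequal number, so part of any genotype difference stays in it. Counts from these splits are thus not a level given by chance alone, and cannot count against a genotype effect. For the stress list the real median was 0.10, splits that follow the batch reached 0.22, and the 5 other batch-balanced splits reached 0.12.

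The rise of autophagy genes is a pattern that several technical explanations could give. A constant offset between replicate 1 and the others falls on both genotypes alike, as each batch holds them in equal number. A rise confined to 1 batch is argued against, since the median was 0.24 over replicates 2 and 3 alone and 0.26 in the replicate 1 pair. Array scaling or noise of dim probe sets is argued against, since the lowest median over 6 scaling and filter alternatives was 0.23. A nitrogen-limited state of the deletion cultures is argued against by 28 nitrogen catabolite repressed genes, whose median was 0.014 (95% bootstrap interval over genes, -0.017 to 0.089). That interval leaves out variation between cultures, and single members were uncertain, with an SE as large as 0.587 for MEP2. No other state of the cultures was tested for this pattern, and such states stay open. The genotype and chance also stay open, since the call was lost with an estimated correlation (adjusted p = 0.148). The real median of 0.27 exceeded the 0.14 reached by any other split. Camera with the preset correlation also called this list in other splits (adjusted p = 2.77e-05, 0.000382, 0.0471 and 0.0475), though not in the rest. A call of the list is therefore not particular to the real split, where the adjusted p was smallest (5.84e-14). The other splits hold both genotypes on each side in unequal number, so part of any genotype difference stays in them. Calls there cannot count against a genotype effect, nor show how often chance gives a call. No test here bears on how Rph1 could act.

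The fall of iron regulon genes stays less settled. A constant batch offset again falls on both genotypes alike. A fall confined to 1 batch is argued against by the median of -0.14 over replicates 2 and 3 and -0.15 in the replicate 1 pair. Iron genes varying together between cultures whatever the genotype stay open, as does a genotype effect, since the set test gave an adjusted p of 0.416 with an estimated correlation. The list's array medians ranged over 0.19 within a genotype against 0.18 between genotypes, and another split gave a median of -0.18, but both follow the batch, and batch-balanced splits other than the real one reached 0.0905 in size. Inside replicates 2 and 3, a range chosen after the wider one was seen, they differed by 0.17 between genotypes against at most 0.017 within one, with only 2 arrays of each.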
